A study of Oryzias melastigma with 12 samples.

How the data were processed

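Total RNA of whole marine medaka larvae was measured on 12 Agilent 4x44K custom arrays with a single dye, Cy3. Marine medaka (Oryzias melastigma) is a small saltwater fish used in toxicity tests. Per the labels' protocols, larvae no older than 24 hours after hatching were kept for 7 days in water with 0.2, 2 or 20 nM hexabromocyclododecane (HBCD, a brominated flame retardant) or with the solvent alone, dimethyl sulfoxide (DMSO) diluted 1 in 30000. Each group had 3 dishes of 100 larvae, and 30 larvae were pooled for each RNA sample. Each array thus stands for 1 pool, and the spread between arrays of a group covers the spread between dishes together with that of the array measurement.

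The authors deposited the scanner output of each array as spot intensities on a linear scale, with no normalization between arrays. Per the file headers the images were read with Agilent Feature Extraction 10.7.3.1, which subtracts the background and removes spatial trends within each array. The submitters' processing notes name version 10.7 of the same program. The authors also deposited a table of log2 values for the same probes. Their columns had nearly the same median (4.34 over the custom probes) and correlated with the log2 processed intensity of their own array at Pearson r of at least 0.999 across probes. The values were therefore on the log2 scale, uncentred and with the direction of the scanner values, with a common distribution as quantile normalization gives. Which program made that table is not given in the sources used here. No column of another sample was present (0 columns).

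Each array held 43277 spots of 26429 custom probes, of which 22407 were printed once, 4014 were printed 5 times and 8 were printed 100 times. The files name the probes only by the number of the custom design, and 0 probes were paired with a gene name. The gene table used here lists 28599 genes, and none of its identifiers could be joined to the probe numbers. For that reason the 30 gene lists fixed before the data were examined, such as xenobiotic metabolism, the thyroid axis and heart contraction, were not tested (0 lists tested), and probes rather than genes are reported.

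The processed intensity was log2 transformed and the 75th percentile of the array's non-control spots was subtracted. Spots marked by the scanner software as non-uniform or as population outliers were left out (507 to 729 spots per array), and the spots of a probe were averaged. A probe counted as well above background on an array when a share over 0.5 of its spots carried that mark. Probes well above background on all 3 arrays of at least 1 group were tested, which left 11910 probes (45.1%). Since under 50% of the probes were detected, scaling to the percentile of the 10429 probes well above background on all 12 arrays was added as an alternative. No spot was saturated (0 spots).

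Groups were compared with limma 3.58.1 in R 4.3.3, with 1 linear model over all 12 arrays, moderated variances, and Benjamini-Hochberg adjustment at 0.05. The comparisons were each concentration against control, a trend over the ordered concentrations coded as equal steps, a moderated F test among the 4 groups, and the 3 differences between exposures adjusted together. Overlap between comparisons that share the control arrays was set beside 200 simulations of unchanged groups. The tests, samples and alternatives were chosen before the data were examined, except those said to have been added.

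The file headers give the slide of each array. Slide 1 held the 3 control arrays and 1 array at 0.2 nM (replicate 3), slide 2 held 2 arrays at 0.2 nM (replicates 1 and 2) and 2 arrays at 2 nM (replicates 2 and 3), and slide 3 held 1 array at 2 nM (replicate 1) and 3 arrays at 20 nM. Each slide had its own scan. Slide was therefore fitted as a block, and groups were also compared within each slide and slides within each group from the means of the 6 combinations present. With these 6 combinations the blocked difference between 20 nM and control is the sum of the 3 steps within slides. A lone array in a combination is assumed to vary like the others.

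Before the data were examined, the rule for named items asked for the largest changes past the threshold whose exposed arrays did not overlap the controls. In the absence of gene names it was applied to probes well above background on all arrays of both groups, limited to 2 that rose and 2 that fell per comparison. Where a probe was not well above background on any array of a group, its fold is a lower bound: the mean of the brighter group over the mean, per array, of the higher of the lowest signal among probes well above background and the probe's own value.

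The fits were tested on simulated data with 200 changed probes. For 20 nM against control with 11886 probes and no slide effect, the fit without a slide term recovered 32.8%, 76.1% and 100% of probes changed by 0.5, 1 and 2 on the log2 scale, with 8 false calls. The fit with slide as a block recovered 0%, 4.48% and 66.7%. When slide effects were simulated as well, the blocked fit recovered 0%, 8.96% and 80.3%, with 3 false calls. The fit without a slide term then recovered 41.8%, 89.55% and 98.5%, with 166 false calls. In both cases the blocked fit detected mainly the large changes. Each case was a single simulated run. The simulated spread was that of the fit without a slide term, which is wider (median residual SD 0.177 against 0.146 with slides). Recovery by the blocked fit may therefore be understated where no slide effect was simulated. With 12 arrays, their number limits the precision. The alternatives covered background correction, scaling, the filter on dim probes, slide and replicate number as blocks, the arrays entering the fit, the variance model, array weights, the deposited log2 table, the thresholds, the dose scale and each array left out in turn. The scanner files give the median but not the mean signal of a spot, so the median was used in normexp background correction.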

Results

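Gene expression was measured in whole marine medaka larvae after 7 days in 0.2, 2 or 20 nM HBCD or in solvent alone, with 3 arrays per group. The 75th percentile of the signal ranged from 293 to 478 intensity units between arrays, and 11551 to 12819 of the 26429 probes were well above background (43.7% to 48.5%). Among probes printed 5 times, the median SD over the spots of an array was 0.085 on the log2 scale. The median SD between arrays was 0.090 in the controls, 0.15 at 0.2 nM, 0.19 at 2 nM and 0.16 at 20 nM (n = 3 each). The groups at 0.2 and 2 nM spanned 2 slides each, so their SDs include slide differences, while the controls and the 20 nM arrays were each on a single slide. These SDs cover all tested probes, of which 9695 were not printed 5 times, so they are not directly comparable with the SD over spots.

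Arrays resembled each other by slide more than by group. Pearson's r across the tested probes averaged 0.9919 over the 10 pairs from different groups on the same slide and 0.9867 over the 4 pairs from the same group on different slides. Replicate 3 at 0.2 nM, which shared slide 1 with the controls, correlated at a mean r of 0.9935 with the controls and 0.9889 with its own group. Replicate 1 at 2 nM, which shared slide 3 with the 20 nM arrays, correlated at 0.9926 with those and 0.9845 with its own group. Probes are not independent replicates, so these values describe the arrays only. Group accounted for 48.0% of the variance among arrays (exact permutation p = 0.00208 over 15400 rearrangements) and slide for 51.2% (exact permutation p = 0.000173 over 5775 rearrangements, the smallest these can give). Group added 18.6% beyond slide, which was not distinguishable from chance when arrays were rearranged within slides (exact permutation p = 0.167 over 96 rearrangements). Slide added 21.8% beyond group. The principal component plot shows the same arrangement.

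**Figure D1:**
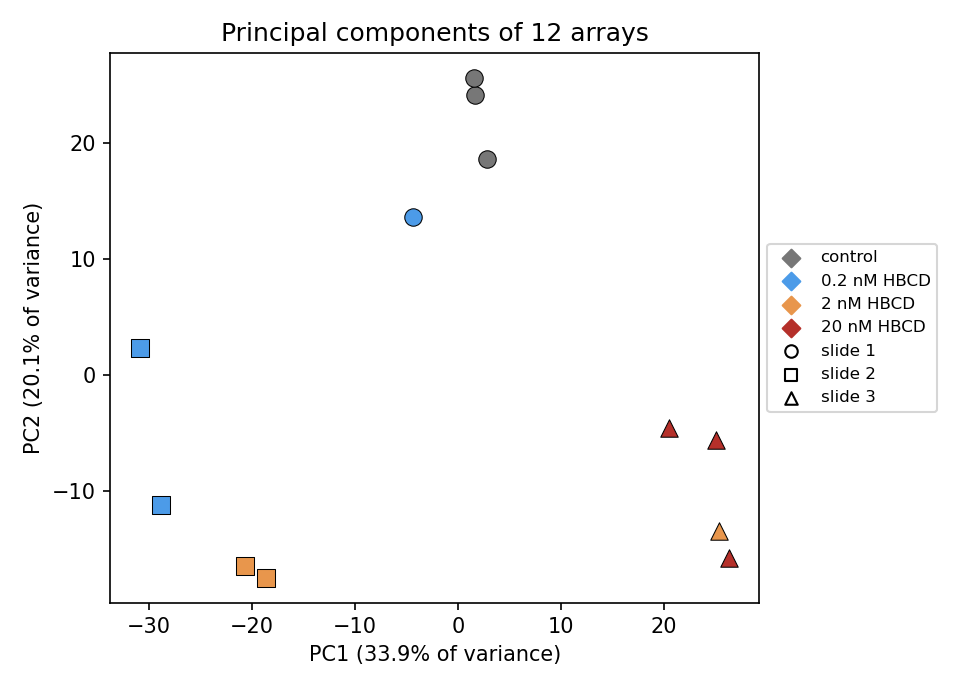
First and second principal components of the 12 arrays over the tested probes, with 33.9% and 20.1% of the variance. Each point is 1 array, colour gives the group and shape gives the slide. The 0.2 nM array on slide 1 lies near the 3 controls, and the 2 nM array on slide 3 lies among the 3 arrays at 20 nM.

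The first comparison asked which transcripts differ after exposure to 0.2 nM HBCD. No probe passed the threshold in limma (0 of 11910 probes, 1774 at an unadjusted p under 0.05, smallest adjusted p = 0.0521). With array weights in the same model 3740 probes passed (1847 higher, 1893 lower). The count was 432 (208 higher, 224 lower) without replicate 3 at 0.2 nM, the only array of that group on the slide of the controls, and at most 5 without any other single array, with 5 reached without control replicate 1. Within slide 1, where that array could be set against the 3 controls, 14 probes passed (12 higher, 2 lower), and the fit with slide as a block, whose contrast is the same, also gave 14. That value rests on 1 exposed array.

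At 2 nM, 325 of 11910 probes differed from control, 289 higher and 36 lower, with a median absolute log2 difference of 0.82. Of these, 117 differed by at least 2-fold. Array weights gave 897 higher and 735 lower, the planned normexp background correction left 0 calls, and without a filter on dim probes 80 passed (69 higher, 11 lower). Probe CUST_18917_PI414333748 was 3.19-fold higher than in controls (log2 difference 1.67, SE 0.27, limma adjusted p = 0.0124), with levels of 0.02 ± 0.25 and -1.66 ± 0.41 relative to the 75th percentile (log2, SD, n = 3 each). Probe CUST_10003_PI414333748 was 3.44-fold higher (log2 difference 1.78, SE 0.33, limma adjusted p = 0.0227). Among the falls, CUST_24709_PI414333748 had a log2 difference of -1.02 (SE 0.15, limma adjusted p = 0.00794) and CUST_19801_PI414333748 of -1.05 (SE 0.24, limma adjusted p = 0.0433). The last of these was the least stable: its limma adjusted p rose to 0.125 without the filter on dim probes, 0.0812 with only the 2 groups in the fit and 0.0698 with repaired normexp, and it lost the call in 9 of the 12 fits without 1 array (highest adjusted p = 0.167). CUST_10003_PI414333748, CUST_18917_PI414333748 and CUST_24709_PI414333748 lost it in 3, 2 and 1 of those fits, and the first and second of them also without the filter (limma adjusted p = 0.0793 and 0.0508). CUST_10003_PI414333748 lost it as well with only the 2 groups in the fit (limma adjusted p = 0.0506). Of the 289 probes that rose, 44 were not well above background on any control array, with differences of at least 1.81-fold at the median and at least 5.07-fold at most. Conversely, 3 probes that fell were not well above background on any array at 2 nM, with differences of at least 3.18-fold at most.

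Few or none of the 2 nM calls held with slide in the model. With slide as a block 1 probe passed, which was not among the 325, and with slide as a random block 24 passed, all 24 among the 325. Over the 325 probes the median difference in the called direction was 0.61 with the block and 0.82 without it. The sign was the same for 99.1% of them, while the median SE over all tested probes rose from 0.14 to 0.22. The blocked value uses the same controls and the 2 nM arrays on slide 2, on which these probes were picked. Agreement in sign was therefore favoured in advance, and its share over all tested probes was not computed. Blocked log2 differences were 0.60 (SE 0.35) for CUST_18917_PI414333748, 0.73 (SE 0.54) for CUST_10003_PI414333748, -1.02 (SE 0.28) for CUST_24709_PI414333748 and -0.97 (SE 0.49) for CUST_19801_PI414333748, with limma adjusted p from 0.358 to 0.734. Within slide 2, CUST_24709_PI414333748 was lower at 2 nM than at 0.2 nM by -0.93 on the log2 scale (SE 0.18, 2 arrays each, limma adjusted p = 0.11). For CUST_18917_PI414333748 and CUST_10003_PI414333748 the same step was -0.16 and -0.38. Single arrays also moved the count: it was 36 without control replicate 2, 113 without control replicate 1, 121 without control replicate 3, 111 and 142 without replicates 2 and 3 at 2 nM, 205 without replicate 3 at 20 nM, and 787 (358 higher, 429 lower) without replicate 1 at 2 nM.

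At 20 nM, 352 of 11910 probes differed from control, 297 higher and 55 lower, with a median absolute log2 difference of 0.90, and 146 differed by at least 2-fold. Array weights turned the balance (1132 higher, 1371 lower), the planned normexp background correction left 1 call, and without a filter on dim probes 71 passed (61 higher, 10 lower). With only the 2 groups in the fit 1158 passed (822 higher, 336 lower). Probe CUST_14751_PI414333748 was 4.25-fold higher (log2 difference 2.09, SE 0.33, limma adjusted p = 0.0119), at 3.02 ± 0.05 against 0.94 ± 0.12 in controls (log2 over the 75th percentile, SD, n = 3 each). Probe CUST_10003_PI414333748, also higher at 2 nM, was 4.23-fold higher (log2 difference 2.08, SE 0.33, limma adjusted p = 0.0137). Probe CUST_4838_PI414333748, a bright probe, had a log2 difference of -1.04 (SE 0.15, limma adjusted p = 0.00836), with levels of 2.89 ± 0.26 against 3.93 ± 0.03. Probe CUST_2364_PI414333748 had a log2 difference of -0.95 (SE 0.19, limma adjusted p = 0.0302). Without the filter on dim probes its limma adjusted p rose to 0.0877 and that of CUST_10003_PI414333748 to 0.053, so both calls were lost. The call of CUST_2364_PI414333748 was lost in 4 of the 12 fits without 1 array, those of CUST_14751_PI414333748 and CUST_10003_PI414333748 in 2 and 1, and that of CUST_4838_PI414333748 in 0. Of the probes that rose, 46 were not well above background on any control array, with differences of at least 1.98-fold at the median and at least 3.46-fold at most, and 5 that fell were not well above background on any array at 20 nM, with differences of at least 1.65-fold at most.

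No probe passed at 20 nM with slide as a fixed or a random block (0 of 11910 in limma each, 740 at an unadjusted p under 0.05 with the fixed block). The median difference over the 352 probes was 0.47 with the block and 0.90 without it. The sign was the same for 93.2% of them, and the median SE over all tested probes rose from 0.14 to 0.27. The same controls and 20 nM arrays picked these probes and enter the blocked value, so here too agreement in sign was favoured in advance. Blocked log2 differences were 0.96 (SE 0.68) for CUST_14751_PI414333748, 0.67 (SE 0.68) for CUST_10003_PI414333748, -0.54 (SE 0.32) for CUST_4838_PI414333748 and -1.36 (SE 0.47) for CUST_2364_PI414333748. The count was 50, 110 and 128 without control replicates 2, 1 and 3, 46, 114 and 115 without replicates 3, 1 and 2 at 20 nM, and 566 without replicate 1 at 2 nM.

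**Figure D2:**
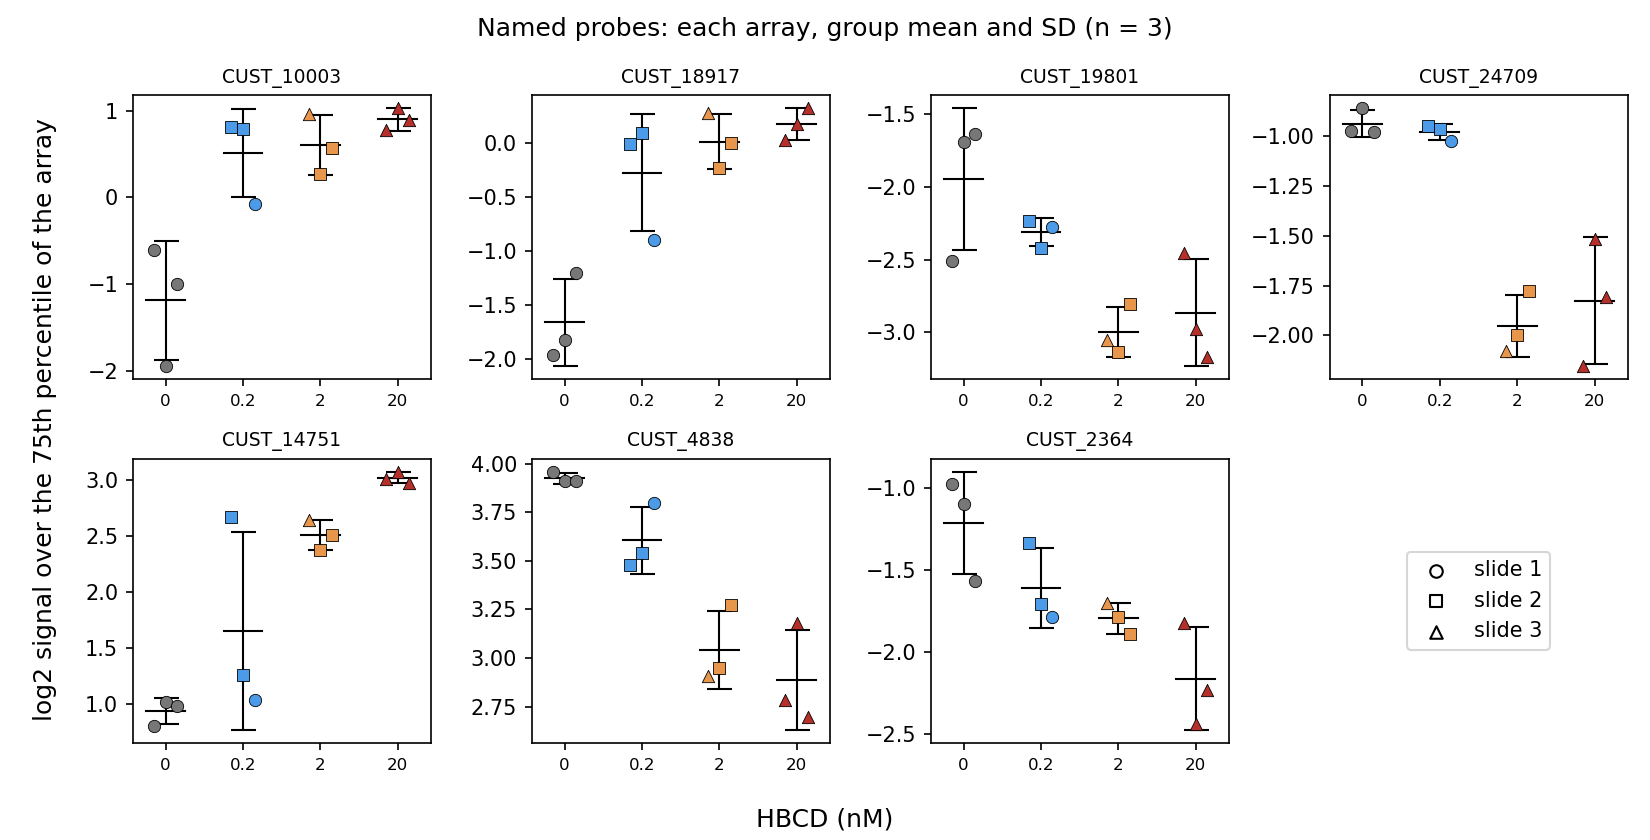
Levels of the 7 named probes on each array, as log2 signal over the 75th percentile of the array, against HBCD concentration in nM. Points are arrays, shapes are slides, and lines with bars are the mean and SD of 3 arrays. CUST_10003 and CUST_18917 were higher on slide 2 than on slide 1 among the 0.2 nM arrays, by 0.88 and 0.94, while CUST_24709 differed there by 0.07.

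Slides were compared within a group to give the size of the slide difference on the same scale. At 0.2 nM, 429 probes differed between slide 2 and slide 1 (42 higher, 387 lower), and at 2 nM, 959 differed between slide 3 and slide 2 (822 higher, 137 lower). Each of these rests on 1 array against 2. Between groups within a slide the counts were 14 for 0.2 nM against control on slide 1, 4 for 2 nM against 0.2 nM on slide 2 (2 higher, 2 lower) and 10 for 20 nM against 2 nM on slide 3 (all 10 lower). At an unadjusted p under 0.05 these counts were 492, 2193 and 412, against 2106 and 2927 between slides, so the step on slide 2 was close in number to the difference between slides 2 and 1. The median absolute difference was 0.18 for that step and 0.20 for those slides. The median SE of all 5 contrasts lay between 0.14 and 0.18. With groups ignored, 5039 probes differed among the 3 slides.

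**Figure D3:**
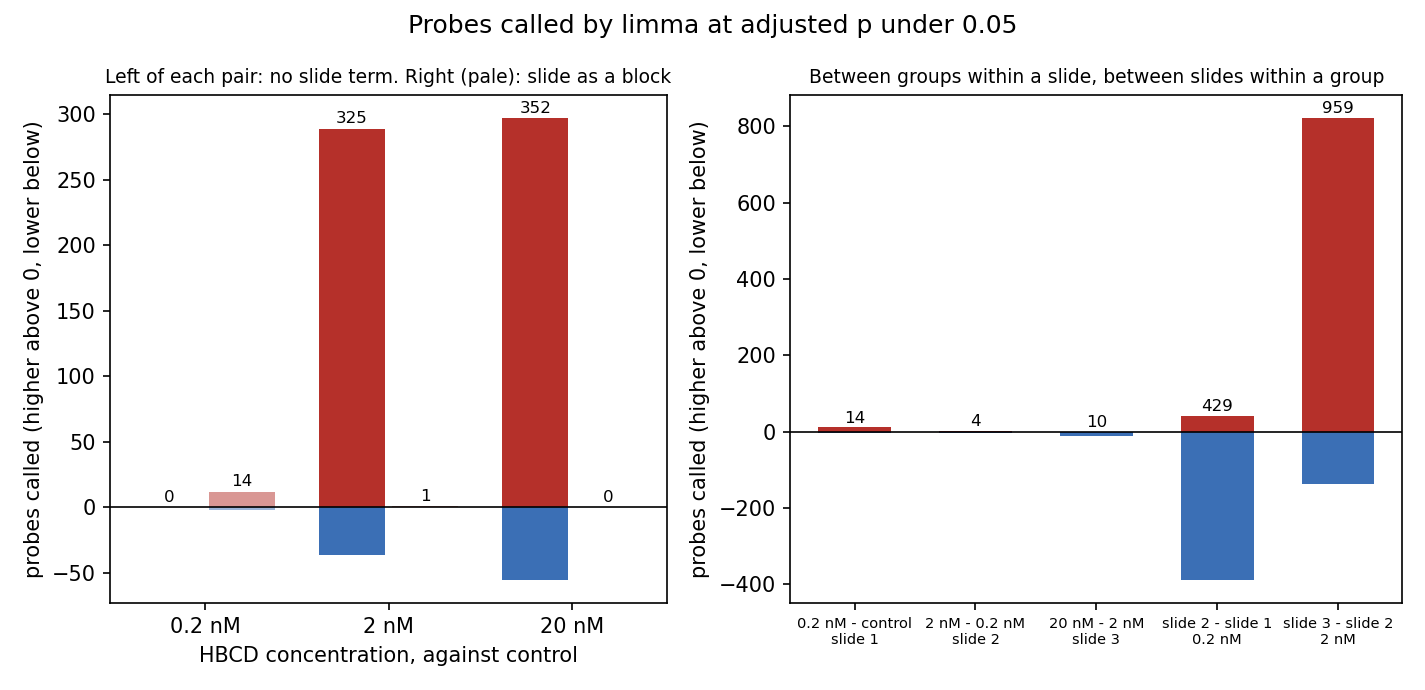
Number of probes called by limma, higher above 0 and lower below 0, with the total printed at each bar. The left panel gives each concentration against control, without a slide term (325 at 2 nM, 352 at 20 nM) and with slide as a block (1 and 0). The right panel gives groups compared within a slide (14, 4 and 10) and slides compared within a group (429 and 959).

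The trend over the ordered concentrations was called for 471 probes, 361 rising and 110 falling, with a median of 0.29 per step on the log2 scale. The balance was 934 rising and 819 falling with array weights, 182 and 129 with scaling to the median, 329 and 170 with quantile normalization and 334 and 177 with the deposited log2 values. Group means moved in a single direction across all 4 groups for 313 of them, and 311 were also called at 20 nM in the same direction. Both counts were favoured in advance, since the 471 probes were picked for a slope on the same arrays. The share with means in a single direction over all tested probes was not computed. CUST_14751_PI414333748 rose by 0.71 per step (SE 0.10, limma adjusted p = 0.00753) and CUST_4838_PI414333748 had a slope of -0.37 per step (SE 0.05, limma adjusted p = 0.00753). The order of the concentrations follows the order of the slides, and 1 probe was called for the trend with slide as a block. With concentration in nM as a linear covariate 0 were called. The count was 65, 119 and 148 without control replicates 2, 3 and 1, and 214 and 287 without replicates 3 and 1 at 20 nM.

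The overall test called 258 probes as differing among the 4 groups, and 18 with slide as a block. It called 9, 11 and 59 without control replicates 3, 2 and 1, 896 without replicate 3 at 0.2 nM, 2248 and 125 without replicates 1 and 2 at 2 nM, and 73, 111 and 141 without replicates 3, 2 and 1 at 20 nM.

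Exposures were then compared with each other, since a probe called at one concentration and not at another is not thereby shown to differ. Adjusted together, the 3 contrasts gave 16 calls on 14 probes: 6 for 2 nM against 0.2 nM, 8 for 20 nM against 0.2 nM and 2 for 20 nM against 2 nM. Adjusted separately, as an added alternative, they gave 17, 1263 (539 higher, 724 lower) and 0. With slide as a block the joint count was 21 (3 higher, 18 lower), against 10 higher and 6 lower without it. The joint count without a slide term was 3708 without replicate 1 at 2 nM, 396 without replicate 3 at 0.2 nM, 75 without replicate 1 at 0.2 nM, 1 without replicate 3 at 2 nM or replicate 1 at 20 nM, and 0 without any single control, without replicate 2 at 2 nM or without replicate 3 at 20 nM.

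Calls at 2 and 20 nM overlapped. Of the rises, 187 were shared, against 7.21 for independent lists of those sizes, and of the falls 13 were shared, against 0.166. No probe was called in opposite directions (0 probes). The same control arrays entered both comparisons. In 20 simulated sets of unchanged groups hardly any probe was called (mean 0.05 at 2 nM and 0 at 20 nM), so they give no usable value for the overlap of calls. With slide as a block 0 calls were shared. The number shared, 200 in all, was 23, 69 and 76 without control replicates 2, 1 and 3, 85 and 112 without replicates 2 and 3 at 2 nM, and 40, 89 and 95 without replicates 3, 1 and 2 at 20 nM. The 3 controls cannot be split into sets of at least 2, so part of the excess over independent lists may come from the shared controls. Across the 11910 probes, fold changes at 2 and 20 nM correlated at r = 0.61, against 0.50 in simulated unchanged groups, and their covariance exceeded the simulated value by 0.064. Without replicate 1 at 2 nM, the array that shared slide 3 with the 20 nM arrays, r was 0.38; no simulation was run for that smaller set of arrays. For 0.2 and 2 nM r was 0.64, against a simulated 0.50, and the excess covariance 0.059. For 0.2 and 20 nM r was 0.25, below the simulated 0.50 (lowest 0.46), and the excess covariance 0.011. That r was 0.060 over the probes well above background on all 12 arrays. It was 0.59 with slide as a block and 0.41 with slide as a random block. The simulated 0.50 was made for the fit without a slide term, so it is no reference for the blocked values. The simulated groups carry no slide differences and concern shared controls only. Arrays that share a slide can move r and the covariance either way. All simulated groups also had the same spread, while the median SD was 0.090 in the controls and 0.15 to 0.19 in the exposed groups. A smaller spread in the controls lowers the r and covariance that shared controls alone give. The simulated 0.50 is therefore likely too high, and the excess covariances may be understated. The r of 0.25 is thus not shown to lie below the value for shared controls. The pairs of concentrations that share slide 2 or slide 3 had the larger covariances, and 0.2 and 20 nM, which share no slide, the smallest.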

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

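Settings marked as added were chosen after the data had been seen. These were the percentile over detected probes, the random slide block, the normexp with replaced backgrounds and the separate adjustment of the exposure contrasts. Counts are given in the order 0.2 nM, 2 nM, 20 nM, trend, among 4 groups, between exposures, shared by 2 and 20 nM, where the reported counts were 0, 325, 352, 471, 258, 16 and 200, and correlations of fold changes are for 0.2 and 2 nM, 0.2 and 20 nM, and 2 and 20 nM, where 0.64, 0.25 and 0.61 were reported. Of the values recomputed for these results, 124 stayed within 1.5 times the reported count or within the spread of the correlation and 150 moved. Of those recomputed for the named probes, 154 stayed past the threshold in the same direction, 53 kept the direction without passing and 1 reversed.

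The planned normexp background correction gave 0 at 2 nM, 1 at 20 nM, 2 for the trend and 0 among groups, between exposures and shared, with correlations of 0.90, 0.098 and 0.21. CUST_19801_PI414333748 at 2 nM reversed, to 0.22 on the log2 scale. On 3 arrays (replicate 1 at 0.2 nM, and replicates 1 and 3 at 2 nM) a few spots had local backgrounds of up to 34763, 28649 and 5911 units against medians of 32.5 to 38, and on these arrays the corrected values correlated with the main values at only 0.93, 0.93 and 0.94. With backgrounds that the scanner software had marked as outliers replaced by the array's median, an alternative added after that outcome had been seen, these correlations were at least 0.988, the counts were 3, 178, 219, 371, 285, 90 and 110, the correlations of fold changes were 0.54, 0.053 and 0.57, and CUST_19801_PI414333748 had a log2 difference of -0.59. The planned form is therefore distorted by those spots, and the repaired form still lowered the counts at 2 and 20 nM.

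Slide as a block gave 14, 1, 0, 1 for the trend, 18 among groups, 21 between exposures (3 higher, 18 lower, against 10 and 6 as reported) and 0 shared, with correlations of 0.59 for 0.2 and 20 nM and 0.84 for 2 and 20 nM. Slide as a random block gave 24 at 2 nM and 0 at 20 nM, for the trend, among groups, between exposures and shared, with correlations of 0.55, 0.41 and 0.73. None of the 8 named probe results passed under either. Scaling to the median gave 3, 174, 207, 311, 115, 5 and 106, and it shifted the median of all tested probes at 20 nM to -0.18, with rises at 75.8% of the calls there. The trend then had 182 rises and 129 falls, against 361 and 110. Scaling over detected probes gave 213 at 2 nM and 0 between exposures. No filter on dim probes gave 2, 80, 71, 111, 45, 1 and 39, with correlations of 0.54 and 0.37 for 0.2 with 2 and 20 nM. The filter for all 12 arrays gave 212 at 20 nM, 296, 28 between exposures and 122 shared, with correlations of 0.57 and 0.060. Both change the number of probes tested.

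Using only the 2 groups compared gave 2, 1158 at 20 nM and 5 between exposures. It equals the reported fit for the trend and the test among groups and was not run for them. A trended and robust variance gave 1 at 0.2 nM and 55 between exposures. Array weights gave 3740, 1632, 2503, 1753, 7317, 7272 and 584, with rises at 45.2% of the calls at 20 nM and correlations of 0.72 for 0.2 and 2 nM and 0.42 for 2 and 20 nM. A minimum of 2-fold gave 117, 146, 191, 98, 6 and 88 from 2 nM on, and a threshold of 0.1 gave 24, 642, 762, 985, 1295, 1664 and 386. Concentration as a linear covariate gave 0 for the trend, and each exposure contrast adjusted on its own gave 1280. Except where the alternative's construction is named, the cause was not tested.

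Replicate numbers did not pair the samples: same-numbered arrays correlated at -0.29 to 0.20 in their deviations from the group means, 3 of 18 pairs exceeded 0.1, and 4 of 12 arrays correlated best with their own number. With replicate number as a block, 162 probes differed among groups and 0 between exposures.

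With each array left out in turn, the ranges were 0 to 432 at 0.2 nM, 36 to 787 at 2 nM, 46 to 566 at 20 nM, 65 to 504 for the trend, 9 to 2248 among groups, 0 to 3708 between exposures and 23 to 278 shared. The correlations ranged from 0.53 to 0.71, 0.20 to 0.33 and 0.38 (without replicate 1 at 2 nM) to 0.71. Quantile normalization and the deposited log2 values moved none of the 7 total counts by over 1.5 times, but raised the falls in the trend from 110 to 170 and 177. Camera with an estimated correlation, fry and the mean of a gene's probes were not run, since no gene list could be tested. Under 50% of probes were well above background, which limits the fold of dim probes to a bound.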

Other observations

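Among the tests below, the rearrangement within slides was added after the other results had been seen, with its outcome bounds written before its own result. The slide 3 test of the share of rises, the limit of 10 calls for a usable share and the separate adjustment of the exposure contrasts were chosen after the results had been seen. No gene names were paired with the probes, so no biological explanation beyond the exposure itself was tested.

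Calls at 2 and 20 nM against control were the first pattern weighed. The slide difference was measured on arrays outside each comparison, over the called probes. At 2 nM it equalled 0.215 of the change from control to the 2 nM arrays on slide 2 (0.18 of 0.82). The direction was the same for 77.8% of 325 probes and for 68.0% of all tested probes. The 2 nM array on slide 3 is left out of this ratio, so a slide part from that array is not covered. At 20 nM the slide difference equalled 0.415 of the change (0.37 of 0.90). The direction was the same for 85.2% of 352 probes and for 65.03% of all tested probes. Both ratios lay below the share of 0.5 set beforehand for a sufficient cause and above the 0.1 set for excluding it. The steps within slides summed to 0.522 of the change at 20 nM. Steps within slides and slide differences add up to the change, so this is mostly the remainder of the same sum and no separate test, and the blocked fit called 0 probes, with a median SE of 0.32 on these. The step from 0.2 to 2 nM within slide 2, on arrays outside the 20 nM comparison, had a median of 0.206 in the called direction. Its direction was the same for 70.5%, short of the 75% set beforehand. The share over all tested probes was not computed for this step, so 70.5% cannot be weighed against the slide shares. Of the 41 called probes printed 5 times, 82.9% changed the same way at every spot. This lies between the 50% and 90% set beforehand, so it leaves local flaws of the array surface open for these 41. They were called on the mean of the same spots, which favours a shared sign. The other 311 calls were on probes not printed 5 times, which this test does not cover. From the ratios above slide and exposure may each contribute and cannot be told apart.

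The excess of rises over falls was the second pattern. At 20 nM it does not come from the choice among the 5 scalings that gave 10 or more calls (planned normexp left 1 call). Rises made up at least 74.9% of the calls there under each of them, against 84.4% as reported. With array weights, which change no scale, the share at 20 nM was 45.2%, and at a threshold of 0.1 it was 69.8%. Scaling did lower the excess for the trend, where rises were 58.5% with scaling to the median, against 76.6% as reported. The share was 80.2% among the 212 probes called after restriction to those well above background on all 12 arrays. The excess at 20 nM was thus not confined to probes near background on some array. That filter kept 10429 of the 11910 tested probes. The 352 probes called at 20 nM were dim, with a median log2 level of -1.80 against -0.23 for all tested, so a part from dim signal is not excluded. Of the 959 probes called between slide 3 and slide 2 at 2 nM, 85.7% were rises. The controls were on slide 1 and the 20 nM arrays on slide 3, so the step from slide 1 to slide 2 also enters at 20 nM. The share of rises over both steps together was not tested, so the slide remains a candidate explanation at 20 nM and no more. Between slide 2 and slide 1 at 0.2 nM the share was 9.79%, below the bound set beforehand for excluding the slide, but that bound covered all probes called between slides, and 78.5% of the 289 rises at 2 nM themselves shifted upward with that slide, so the test leaves the question open at 2 nM. Without replicate 1 at 2 nM, falls outnumbered rises at 2 nM (429 against 358).

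The third pattern was the 1263 probes called between 20 and 0.2 nM when that contrast was adjusted on its own. The difference between slide 3 and slide 2 at 2 nM was taken on arrays outside the contrast. It equalled 0.474 of the change from 0.2 nM on slide 2 to 20 nM on slide 3 (0.29 of 0.61). The 0.2 nM array on slide 1 is left out of this ratio. The slide difference had the same direction as the change for 91.9% of the probes. Over all tested probes the same direction was found for 76.4%. The ratio fell just short of the 0.5 set beforehand, so slide and concentration cannot be told apart here.

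Other splits of the arrays into groups of the same sizes were fitted in the same way. For 0.2 nM against control all 10 splits gave 0 calls. For 2 nM the real split gave 325 and the highest other 0 (1 of 10 splits as large), and for 20 nM the real split gave 352 and the highest other 1 (1 of 10 splits as large). With 10 splits the share cannot fall under 0.05. For the trend, 1 of 100 splits, the real one, reached 471, with 258 the highest other, and for the test among the 4 groups 2 of 100 reached 258, with 361 the highest other, so chance was excluded for both among splits that ignore the slides. Those splits break up the slides, which the real grouping follows. When arrays were rearranged only within slides, 10 of the 96 rearrangements gave at least 471 calls for the trend (highest other 1188) and 6 of the 96 gave at least 258 among the 4 groups (highest other 1849), so chance was not excluded for either once slides were kept together. With slide as a block the counts were 1 and 18. Of the free splits for the test among groups, 2 held more pairs of arrays sharing group and slide than the real one (9 pairs, against 8). They gave 361 and 3 calls, so the number of such pairs alone did not set the count. For the trend the split with 9 such pairs gave 0. For the differences between exposures 9 of 100 splits reached the real 16, so chance was not excluded. In that result the 7 splits with 9 such pairs gave 363 to 3244 calls and the highest of the remaining splits gave 72, which points to the slide as a structure of the exposed arrays.

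Simulated arrays with a correlation of 0.36 within slides and no exposure effect gave a mean of 24.2 and at most 57 calls for 20 nM against control in 20 simulations. This simulation assumes the same correlation for all probes and excludes nothing about the slides.

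Calls were rarer among probes printed 5 times than among the others, at 1.49% against 3.01% at 2 nM (Fisher's exact p = 3.37e-05, two-sided). At 20 nM the shares were 1.85% and 3.21% (Fisher's exact p = 0.00048, two-sided). Fisher's test treats probes as independent, but all were measured on the same 12 arrays, so these p-values describe these arrays only. Signal levels of the 2 kinds of probe were not compared. The mean of a fixed selection of spike-in control probes lay between 3.15 and 3.72 above the 75th percentile on the log2 scale. It was lowest on replicate 2 at 2 nM. This mean lay at 3.61 to 3.64 on slide 1, 3.15 to 3.72 on slide 2 and 3.38 to 3.49 on slide 3. The slide of the controls and that of the 20 nM arrays thus did not overlap in this measure.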
